A study of Mus musculus with 2 samples.

How the data were processed

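Total RNA-seq after ribosomal RNA depletion was measured in the nucleoplasmic fraction of bone marrow-derived macrophages given lipid A at 100 ng/ml for 25 min. The description calls the fraction nucleoplasmic and another label calls it nuclear. Per the labels, 500 ng of RNA went into the library of replicate 1 and 1 µg into that of replicate 2, and the fragment size range was 250 to 400. Each library had a gene table and 2 transcript tables. Expected counts and TPM in the gene table and in the first transcript table were made by the authors from an alignment to the transcriptome, per the deposited readme, with assembly mm10 and GENCODE annotation M21. Percent of a gene's TPM in each transcript is a column of that deposited transcript table. The second transcript table holds estimated counts and TPM made by the authors directly from the reads and an index, with no alignment between, per the deposited readme. It is called the alignment-free table here. The names of the quantifiers are not given in the sources used here. The column names are those that RSEM and kallisto write. The interval bounds of TPM in the gene and transcript tables were not used. Replicates were not pooled.

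The annotation for gene types, transcript types, coordinates and lengths was GENCODE M21, and all 55536 Ensembl gene rows were found in it. Rows that are no annotated gene stayed out of all totals: a phiX row (0.350% and 0.0784% of all counts in replicates 1 and 2), 96 ERCC rows with 0 counts, and 26248 rows with a number as identifier. TPM was used as deposited, over all rows, so short RNAs and mitochondrial genes take part of each library's total. Genes under 200 bases held 0.398% of counts and 24.8% of TPM. Genes that share sequence with copies elsewhere, and genes that overlap others, have uncertain counts because the quantifier splits shared reads between them. Whether counting used strand is not given in the sources used here. Depth was 13506939 and 17932332 estimated counts in the gene table and 25372491 and 26328920 in the alignment-free table. The median difference between length and effective length of genes over 1000 bases was 215 bases in replicate 1 and 184 in replicate 2. A count of 0 was read as allowing up to 3 counts. Intervals of shares are 95% Wilson intervals, and both cover counting error only, since reads without molecular identifiers are not independent molecules.

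Both libraries form 1 group, so no test between groups, no paired test and no p-value was computed. The design, the alternatives, 25 gene lists and the rule for named genes were fixed before the data were examined. A list's level is the median over members of log2(TPM + 1). Its percentile is among 10000 random lists of protein-coding genes with the same number of members per decile of gene length. Log2 ratios of replicate 2 to replicate 1 used TPM + 1 and genes with at least 10 estimated counts in both. List medians of these ratios were ranked among 10000 random lists matched on mean expression in 20 bins, for lists with at least 3 countable members. All percentiles describe these libraries. For TMM factors, DESeq2 size factors and the edgeR common dispersion the estimated counts were rounded to whole numbers. The chi-square of counts used genes with at least 20 counts over both libraries. Where a symbol names several genes, the one with the higher TPM was used. Of the listed symbols, 2 were not found in the table.

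The lists cover immediate early transcription factors, early cytokines, the NF-kB family and its feedback, MAP kinase feedback and mRNA decay, late inflammatory genes, the interferon response and TLR4 signalling. They also cover macrophages, 7 other cell types, nuclear long noncoding RNAs, small nucleolar RNA hosts, structured small RNAs, inducible noncoding genes, mitochondrial mRNAs, housekeeping, heat shock, cell cycle, ribosomal protein and replication-dependent histone genes. Named genes are the up to 4 members of each list with the highest mean TPM, and for the 6 lipid A lists also the 2 lowest. They further include the 10 highest genes, the 10 highest protein-coding genes, the 5 largest ratios between the libraries each way with at least 100 counts in both, and Tnf, Il6, Il1b, Ifnb1, Fos, Egr1, Nfkbia, Malat1, Neat1 and Xist. Some named genes of lists that are not about lipid A are left out of the text. Where a gene outside the rule is named, the text says so.

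Alternatives were a pseudocount of 0.1 TPM, other minimums of TPM or counts, rescaled TPM without mitochondrial genes and genes under 200 bases, CPM, the alignment-free table, other random lists, means in place of medians, TMM and DESeq2 scaling, and each library alone. The alignment-free table rescaled in the same way, ratios minus their median, alignment-free list ratios over the genes countable in the gene table, and means or rescaled TPM for the differences between lists were chosen after seeing the data. The counting of genes beyond 2-fold was tested on simulated counts drawn from the real means and library sizes with the edgeR dispersion and 200 changed genes, over 14827 simulated genes with at least 10 counts in both libraries. It counted 49 of 50 genes raised 4-fold, 45 of 50 lowered 4-fold, and 0.534% of unchanged genes. Of genes changed 1.5-fold it counted 4 of 50 raised and 5 of 50 lowered. Simulated ratios were taken minus their median, with 1 effective length per gene for both libraries. These rates therefore apply to counts of genes after subtracting the median and not to counts without that step. The changed genes, and the members of the simulated lists, were drawn from genes with a mean of at least 100 counts. Recovery was not measured for genes with fewer counts. A simulated list of 15 genes raised 1.5-fold lay at percentile 99.1, and 5 of 200 unchanged lists lay outside the central 95%. Simulated genes varied independently with 1 common dispersion, so this gives no rate for lists of genes that vary together. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.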

Results

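The data were 2 ribosomal RNA-depleted total RNA-seq libraries from the nucleoplasmic fraction of mouse bone marrow-derived macrophages. The cells, primary macrophages of strain C57BL/6J, had been given lipid A at 100 ng/ml for 25 min. Lipid A is the part of bacterial lipopolysaccharide that the receptor TLR4 recognises. Both libraries belong to this 1 group and carry separate biological replicate numbers but the same donor entry, so the SDs measure the spread between these libraries. The series as analysed here has no untreated, whole-cell or other-time group, so the values below are levels in treated cells and no induction was measured. The gene table held 13506939 estimated counts on annotated genes in replicate 1 and 17932332 in replicate 2. A count of 0 allows up to 0.222 and 0.167 CPM in them, where CPM is the estimated count scaled to a total of 1e+06. Values are mean ± SD over these libraries (n = 2) unless a library is named, and no test between conditions was possible. At a TPM of at least 1 in both, 12507 of 55536 genes were detected, among them 9806 of 22028 protein-coding genes (44.5%). With a TPM of at least 5 these counts were 7115 and 6294.

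The first comparison asks which parts of the lipid A response were present in the nucleoplasmic fraction at 25 min. Transcripts of early response genes were abundant and those of most late inflammatory genes were near 0. The early cytokine list had a median log2(TPM + 1) of 7.01 ± 0.059, the immediate early transcription factors 6.54 ± 0.17, the genes that restrain MAP kinases or destabilise mRNA 5.41 ± 0.040, and the NF-kB family and its inhibitors 5.34 ± 0.047. The late inflammatory list had 0.66 ± 0.019. Each of the 4 early lists lay at percentile 100 of 10000 random lists of protein-coding genes matched on length, and the late inflammatory list at percentile 61.0. The housekeeping and macrophage lists also lay at percentile 100, so this rank shows that the genes were expressed and not that lipid A induced them. Within a library, the early cytokines exceeded the late list by 6.34 ± 0.079 log2 units, the immediate early factors by 5.87 ± 0.15, the MAP kinase and mRNA decay list by 4.75 ± 0.059 and the NF-kB list by 4.68 ± 0.028. All 4 differences were larger than the spread between the libraries. With a pseudocount of 0.1 TPM the late list had a median of -0.55, below 1 TPM.

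**Figure D1:**
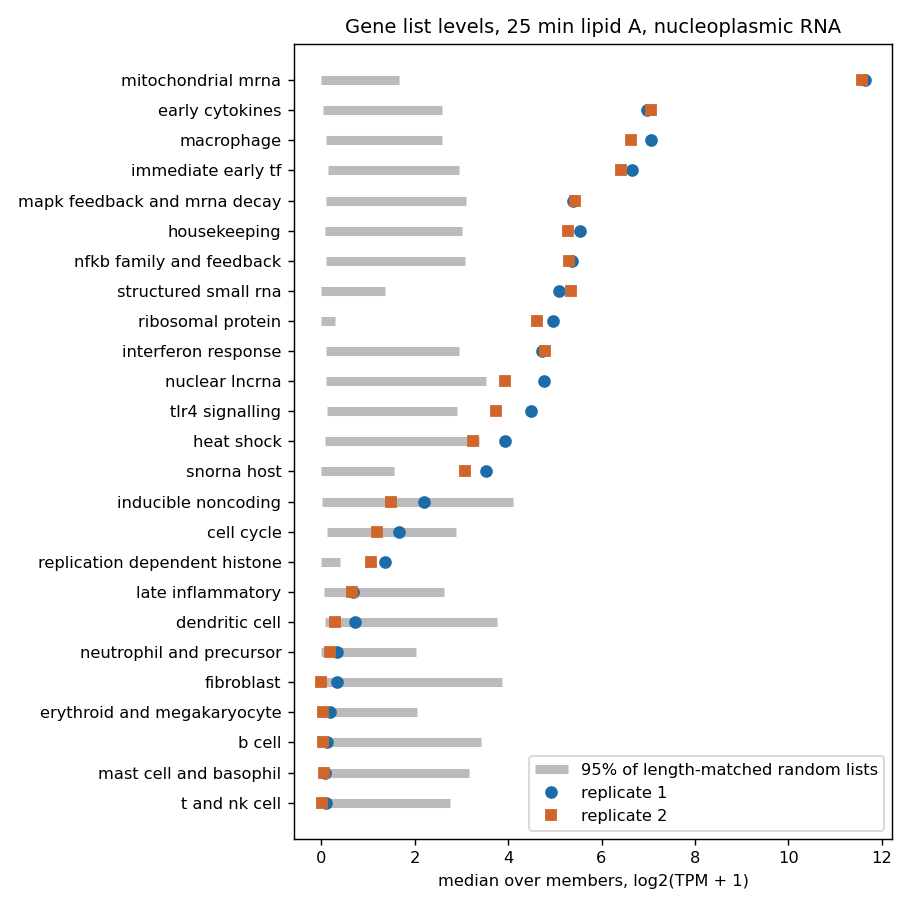
Median log2(TPM + 1) over the members of each gene list (x axis) for the 25 lists (y axis). Circles are replicate 1, squares replicate 2, and grey bars hold 95% of the length-matched random lists. The early cytokine list is at 6.97 and 7.05 and the late inflammatory list at 0.68 and 0.65.

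Among the early cytokines, 14 of 15 were detected. The neutrophil chemokine Cxcl2 had 649.9 ± 61.2 TPM and Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007, mm10), the cytokine tumour necrosis factor, had 592 ± 47.3. Il1b, the precursor of interleukin-1 beta, had 445 ± 62.0 and Tnfsf9, the ligand of the costimulatory receptor 4-1BB, 305 ± 86.9. The lowest members were Csf1 at 43.9 ± 5.51 and Lif at 0.660 ± 0.735 TPM. Lif rested on 20 and 12 counts. Of the immediate early factors, 21 of 22 were detected. The nuclear receptor Nr4a1 had 389 ± 58.7 TPM, the AP-1 subunit Fos (ENSMUSG00000021250.13, chromosome 12, 85473890 to 85477273, mm10) 349.9 ± 151, its partner Junb 327 ± 6.62 and the zinc finger factor Egr1 288 ± 19.4. Fos had 457 TPM in replicate 1 and 243 in replicate 2. Srf, which itself drives immediate early genes, had 5.63 ± 0.467 and Klf4 0.690 ± 0.453.

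In the NF-kB list 16 of 16 were detected. Nfkbia (ENSMUSG00000021025.8, chromosome 12, 55489410 to 55492647, mm10), which encodes the inhibitor IkB alpha, had 559 ± 134 TPM. The ubiquitin-editing enzyme gene Tnfaip3 had 479.9 ± 20.4, the nuclear IkB protein gene Nfkbiz 449 ± 19.3 and its relative Nfkbid 154 ± 0.884. The lowest, the deubiquitinase gene Cyld and the adaptor gene Traf1, had 19.9 ± 7.94 and 15.7 ± 0.127. In the list of MAP kinase feedback and mRNA decay genes 16 of 17 were detected. Zfp36, whose product binds AU-rich elements and promotes mRNA decay, had 519 ± 10.8 TPM. The stress phosphatase subunit gene Ppp1r15a had 499 ± 8.06, and the MAP kinase phosphatase genes Dusp1 and Dusp2 had 368 ± 2.74 and 333 ± 41.6. Dusp6 and Spry1 were at 1.94 ± 0.290 and 0.555 ± 0.0919.

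With 1 time point, whether a member of the late inflammatory list responds late in these cells was not measured. Of the genes placed in that list before the data were examined, 3 of 17 were detected. These were Ptgs2, which encodes cyclooxygenase-2, at 43.4 ± 25.4 TPM, Acod1, which encodes the enzyme that makes itaconate, at 14.1 ± 7.68, and the chemokine gene Ccl5 at 6.87 ± 3.03. Saa3, an acute phase gene, had 0.690 TPM in replicate 1 and 4.89 in replicate 2. Il6 had 0.990 ± 0.311 TPM from 31 counts in each library. Nos2, the inducible nitric oxide synthase gene, had 2 and 10 counts, and Il12a had 0 and 1, under the 3 counts that a count of 0 allows.

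**Figure D2:**
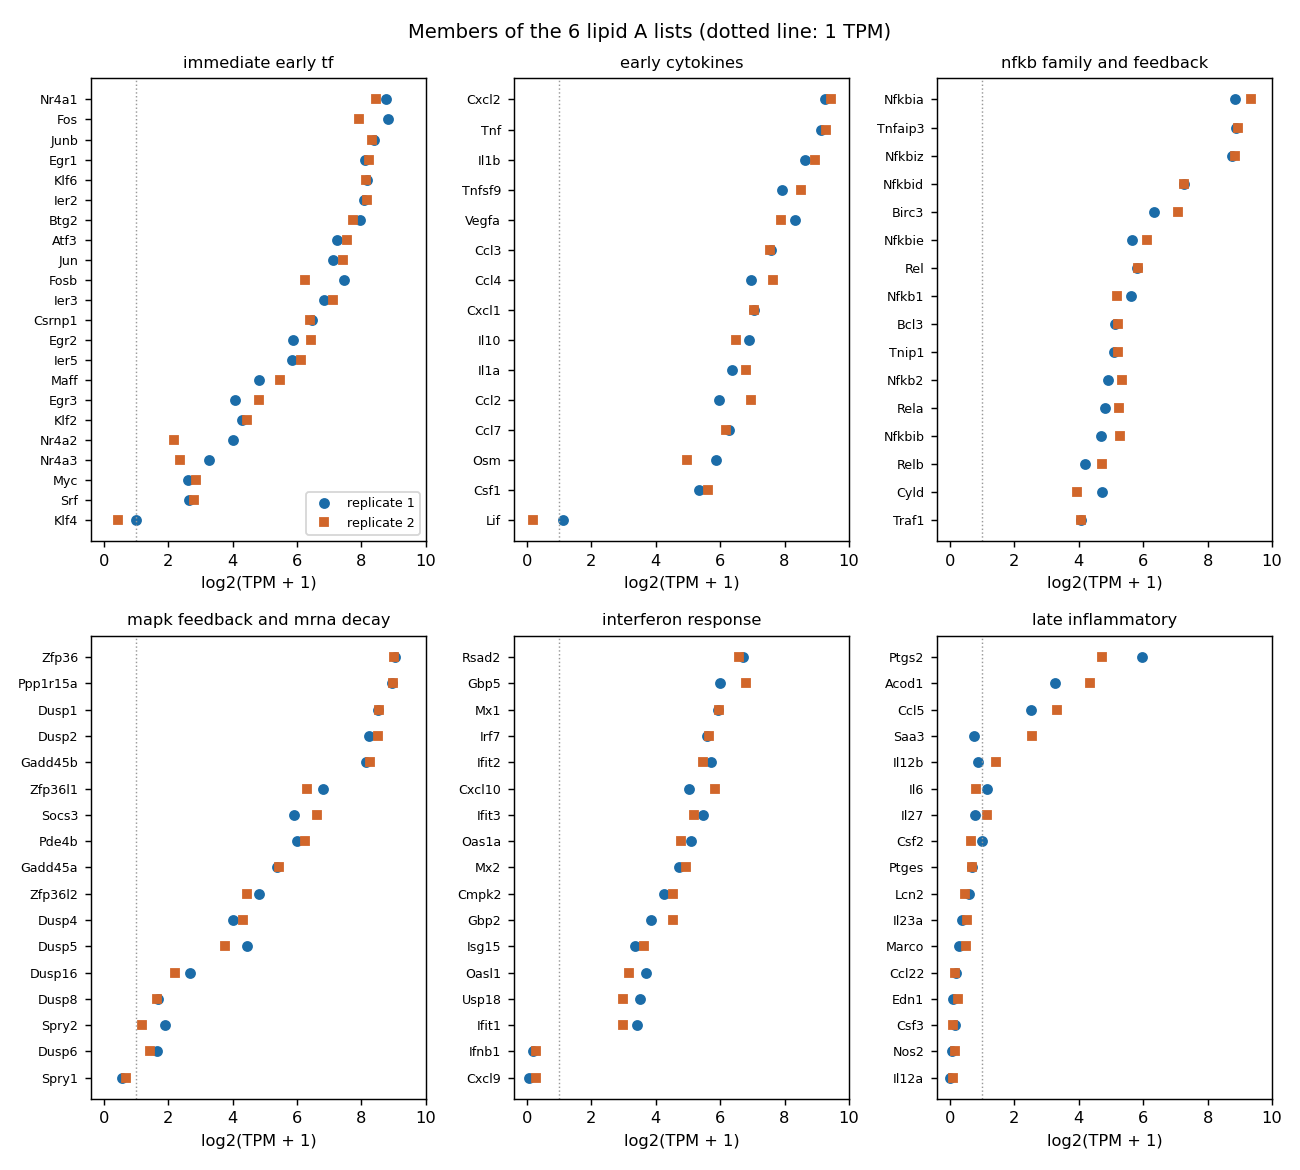
Log2(TPM + 1) (x axes) of every member of the 6 lipid A lists (y axes), with replicate 1 as circles and replicate 2 as squares. Most late inflammatory members lie left of the dotted line at 1 TPM, with Ptgs2, Acod1 and Ccl5 right of it, while Tnf had 558 and 625 TPM.

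Genes of the interferon response were present at intermediate levels while the interferon beta gene itself was near 0. The list had a median of 4.76 ± 0.050, percentile 100, with 15 of 17 members detected. The antiviral genes Rsad2 and Mx1 had 99.9 ± 6.59 and 60.5 ± 1.24 TPM, the guanylate-binding protein gene Gbp5 86.9 ± 34.2 and the interferon regulatory factor gene Irf7 48.3 ± 1.43. Ifnb1 had 1 count in replicate 1 and 3 in replicate 2, and Cxcl9 had 2 and 13. The early cytokines exceeded the interferon list by 2.25 ± 0.0096 log2 units, the immediate early factors by 1.78 ± 0.22, the MAP kinase and mRNA decay list by 0.65 ± 0.0097 and the NF-kB list by 0.58 ± 0.097. In CPM the early cytokine difference was 1.47. The NF-kB difference was 1.23 in CPM, 1.18 in the alignment-free table and 1.71 as a mean over members.

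The next comparison sets macrophage markers beside those of other marrow cells. Macrophage genes were high and lineage markers of other cells were near 0 in the gene table, apart from a few led by Pf4. The macrophage list had a median of 6.84 ± 0.31 (percentile 100, 22 of 23 detected). Lysozyme gene Lyz2 had 1648 ± 85.0 TPM, Apoe, an apolipoprotein gene, 856 ± 175, the CSF-1 receptor gene Csf1r 642 ± 172 and the perforin-like gene Mpeg1 639 ± 149. Medians of the other lists were 0.26 ± 0.10 for neutrophils and their precursors (2 of 11 detected, percentile 75.7), 0.52 ± 0.30 for dendritic cells (0 of 8, percentile 26.9) and 0.087 ± 0.062 for B cells (0 of 8, percentile 5.13). They were 0.063 ± 0.068 for T and NK cells (0 of 10, percentile 13.0), 0.069 ± 0.018 for mast cells and basophils (0 of 6, percentile 20.2) and 0.17 ± 0.24 for fibroblasts (0 of 7, percentile 18.7). The erythroid and megakaryocyte list had 0.11 ± 0.095 (3 of 11, percentile 38.5), and its member Pf4, a platelet chemokine gene, had 59.3 ± 15.5 TPM. The neutrophil gene S100a9 had 1.65 ± 0.0990 and Kit, a mast cell and progenitor receptor gene, 1.58 ± 1.39. Detection here is that of the gene table. In the alignment-free table Cd3d of the T and NK list had 8.72 and 1.10 TPM from 520 and 227 counts, against 2 and 1 gene-table counts. Cd8a of that list had 1.43 and 0.313 TPM there, under 1 TPM in replicate 2. Cd3d is outside the naming rule and was chosen after its values were seen. Genes of the TLR4 pathway had a median of 4.12 ± 0.53 (percentile 100.0, 21 of 22 detected), led by the co-receptor gene Cd14 at 432 ± 64.4.

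The libraries carried large shares of nuclear noncoding RNA. Protein-coding genes took 75.3% ± 3.78 of the estimated counts. The list of nuclear long noncoding RNAs took 13.4% ± 0.523, mostly Malat1 (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672, mm10), a nuclear speckle RNA, with 10.4% ± 0.308. The paraspeckle RNA Neat1 took 1.91% ± 0.134, and Xist, the RNA that coats the inactive X chromosome, 0.622% ± 0.0220. The list of structured small RNAs took 2.20% (2.19% to 2.21%) in replicate 1 and 5.38% (5.37% to 5.39%) in replicate 2, with 95% Wilson intervals that cover counting error only. Of this, Rn7sk, the RNA that holds the elongation factor P-TEFb inactive, took 1.37% (1.36% to 1.38%) and 3.88% (3.87% to 3.89%). Mitochondrial-encoded genes took 4.87% ± 0.268, ribosomal protein genes 0.173% ± 0.00876 and replication-dependent histone genes 0.0127% ± 0.000452. TPM divides counts by length and so gives short RNAs more weight. As shares of TPM, the structured small RNAs took 26.2%, the nuclear long noncoding RNAs 2.70% and the ribosomal protein genes 0.268%.

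The remaining lists describe the other RNA of this fraction. Mitochondrial mRNAs, which are made in mitochondria and not in the nucleus, had the highest list median, 11.61 ± 0.047 (percentile 100), with mt-Co1, a cytochrome oxidase subunit gene, at 12382 ± 2685 TPM. With mitochondrial-encoded genes at 4.87% ± 0.268 of counts, the levels given here are those of the fraction as prepared and not of nuclear RNA alone. The highest gene of the gene table was Rn7sk at 157312 ± 63039.7 TPM. In the alignment-free table it had 44703.6 and 29922.5 TPM and was not the highest gene. Outside the mitochondrial genome, the members of the 10 highest protein-coding genes were the lysosomal protein gene Psap at 4412 ± 882 and the glycoprotein gene Gpnmb at 2682 ± 441. Medians were 5.41 ± 0.19 for housekeeping genes (percentile 100), 4.79 ± 0.24 for ribosomal protein genes (percentile 100), 3.59 ± 0.48 for heat shock genes (percentile 98.7) and 3.30 ± 0.31 for hosts of small nucleolar RNAs (percentile 100.0). Cell cycle genes had 1.42 ± 0.33 (percentile 64.2), replication-dependent histone genes 1.22 ± 0.21 (percentile 100.0), inducible noncoding host genes 1.85 ± 0.49 (percentile 71.1), nuclear long noncoding RNAs 4.35 ± 0.59 (percentile 99.8) and structured small RNAs 5.22 ± 0.19 (percentile 100). Among random lists of detected genes the percentiles were 64.7 for heat shock, 72.4 for small nucleolar RNA hosts, 2.23 for inducible noncoding and 0 for cell cycle genes. The histone genes were at percentile 0 there, and at 81.5 among protein-coding lists not matched on length.

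The transcript table shows how much of each gene's signal was assigned to transcripts annotated as retaining an intron. For all protein-coding genes that share of counts was 15.5% ± 0.676. Genes without an annotated transcript of this kind count as 0. The share was 20.9% ± 1.93 for the early cytokines, 20.9% ± 0.512 for the NF-kB list, 21.3% ± 3.52 for the interferon list and 14.9% ± 0.574 for the MAP kinase and mRNA decay list. It was 4.39% ± 0.786 for the immediate early factors, 3.71% ± 0.273 for the macrophage list and 0.969% ± 0.803 for the late inflammatory list. These are shares of all counts of a list, so genes with many counts weigh most. Such a transcript is annotated for 5 of 22 immediate early genes, 9 of 23 macrophage genes and 4 of 17 late genes. It is annotated for 6 of 15 early cytokines, 12 of 16 NF-kB genes, 9 of 17 interferon genes and 6 of 17 MAP kinase and mRNA decay genes. Over genes with such a transcript and at least 10 counts in both libraries, the median share was 17.4% for all protein-coding genes and 13.2% for the 5 immediate early genes. It was 39.9% for the early cytokines, 31.7% for the interferon list and 22.0% for the NF-kB list. For the MAP kinase and mRNA decay list it was 17.6%, and for the macrophage list 5.53%. The only such late gene, Ccl5, had 60.7%. The hosts of small nucleolar RNAs had 64.7% ± 0.788 and the ribosomal protein genes 24.9% ± 0.711. Single genes ranged widely: retained-intron transcripts took 88.1% ± 4.10 of the counts of Dusp1, 66.8% ± 0.700 of Cxcl2, 62.4% ± 9.55 of Gbp5 and 53.9% ± 1.65 of Tnfaip3. Whether these reads came from transcripts that keep the intron or from RNA not yet spliced was not tested. In the alignment-free table the late inflammatory share was 3.27%. Of the 106 genes chosen by the rule with a mean TPM of at least 1, 86 had the same leading transcript in both transcript tables. The leading transcript held a median of 82.0% of the gene's TPM, and 66.8% in the alignment-free table.

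**Figure D3:**
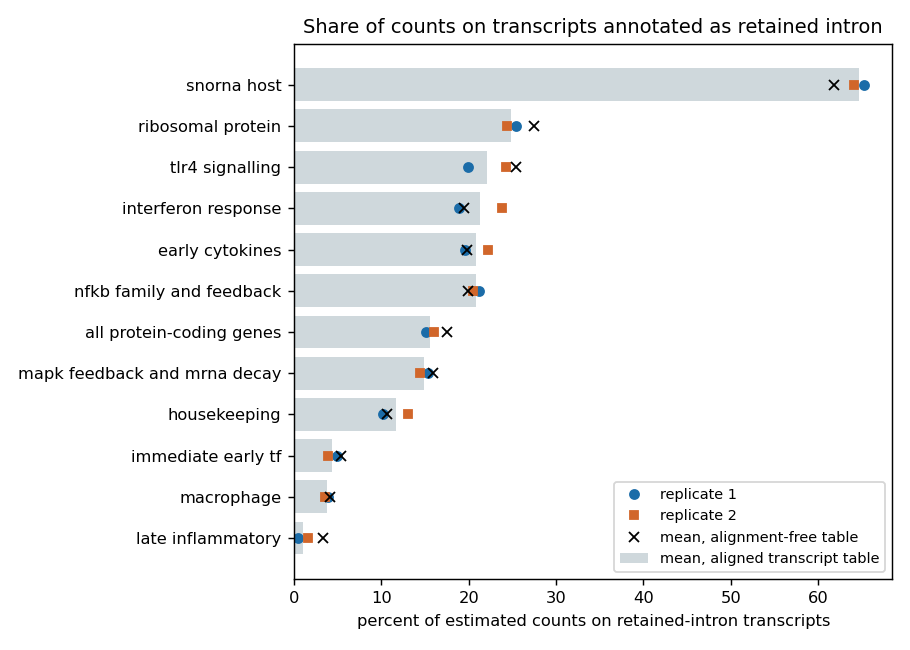
Percent of estimated counts on retained-intron transcripts (x axis) for gene lists (y axis). Bars are means of the 2 libraries, circles replicate 1, squares replicate 2 and crosses the mean in the alignment-free table. Hosts of small nucleolar RNAs stand at 64.7% and the macrophage list at 3.71%.

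The last comparison is between the libraries, with 1 library on each side and so no test. Across all genes, log2(TPM + 1) had a Pearson r of 0.971 and a Spearman rho of 0.832. These are across genes, which are not independent replicates. Their counts differed by more than sampling noise, with a chi-square of 52.3 per degree of freedom, so they were kept as 2 samples. The edgeR biological coefficient of variation was 0.191. The median log2 ratio of replicate 2 to replicate 1 was -0.42 over 14584 genes with at least 10 counts in both. On that scale 52 genes were over 2-fold higher in replicate 2 and 518 over 2-fold lower. After subtracting the median, a step chosen after seeing the data, these were 178 and 71. They were 241 and 65 with TMM scaling, and 420 and 278 with DESeq2 size factors. In the alignment-free table minus its own median, also chosen after seeing the data, 623 genes were over 2-fold higher and 694 over 2-fold lower.

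Relative to the median of all genes, the lipid A lists were higher in replicate 2 in the gene table, while in the alignment-free table the immediate early list (-0.046) and the NF-kB list (-0.031) lay below the median of the genes countable there. Against the median of the genes countable in the gene table, a step chosen after seeing the data, these alignment-free values were 0.12 and 0.13. The list medians were 0.59 log2 units for the early cytokines (percentile 100.0 of random lists matched on expression), 0.53 for the immediate early factors (100), 0.53 for the NF-kB list (100) and 0.44 for the MAP kinase and mRNA decay list (100.0). In the alignment-free table the early cytokines stood at 0.17 and the MAP kinase and mRNA decay list at 0.042, or 0.33 and 0.20 against the genes countable in the gene table. The interferon list stood at 0.46 (percentile 100), or 0.019 in the alignment-free table. The 7 countable late inflammatory genes stood at 0.97 (percentile 100), or 0.65. Structured small RNAs were at 1.14 (percentile 100), the 3 inducible noncoding genes at 0.66 (98.5) and ribosomal protein genes at 0.20 (100), the last at -0.37 in the alignment-free table. Structured small RNAs and the inducible noncoding genes stood lower in the alignment-free table, but above its median. The macrophage list was at 0.080 (percentile 64.2), or -0.39 in the alignment-free table, the TLR4 pathway at -0.029 (47.2) and nuclear long noncoding RNAs at -0.11 (8.14). In the alignment-free table the nuclear long noncoding RNAs were at -0.37, and the TLR4 pathway also stood lower than in the gene table. Among genes with at least 100 counts in both libraries, the largest ratios against the median were in the mitochondrial ribosomal RNA genes mt-Rnr2 (3.92) and mt-Rnr1 (2.92). Their combined share of counts was 0.0756% (0.0741% to 0.0770%) in replicate 1 and 0.805% (0.801% to 0.809%) in replicate 2. The other ribosomal RNA genes took 0.0105% and 0.0490%, and CT010467.1 among them was at 1.99. In the alignment-free table CT010467.1 had 37529 and 46120 counts, and its TPM fell from 1648 to 542, more than the median there. Its rise therefore depends on the quantification. The TPM of mt-Rnr2 and mt-Rnr1 rose in that table too, from 246 to 712 and from 332 to 674. Both libraries were depleted of ribosomal RNA, so uneven depletion cannot be told apart from a difference in RNA level. The 5 lowest included the unprocessed pseudogenes Gm28438 (-2.02) and Gm28439 (-1.94), which can share reads with their source genes, and the zinc finger gene Zfp993 (-1.79).

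**Figure D4:**
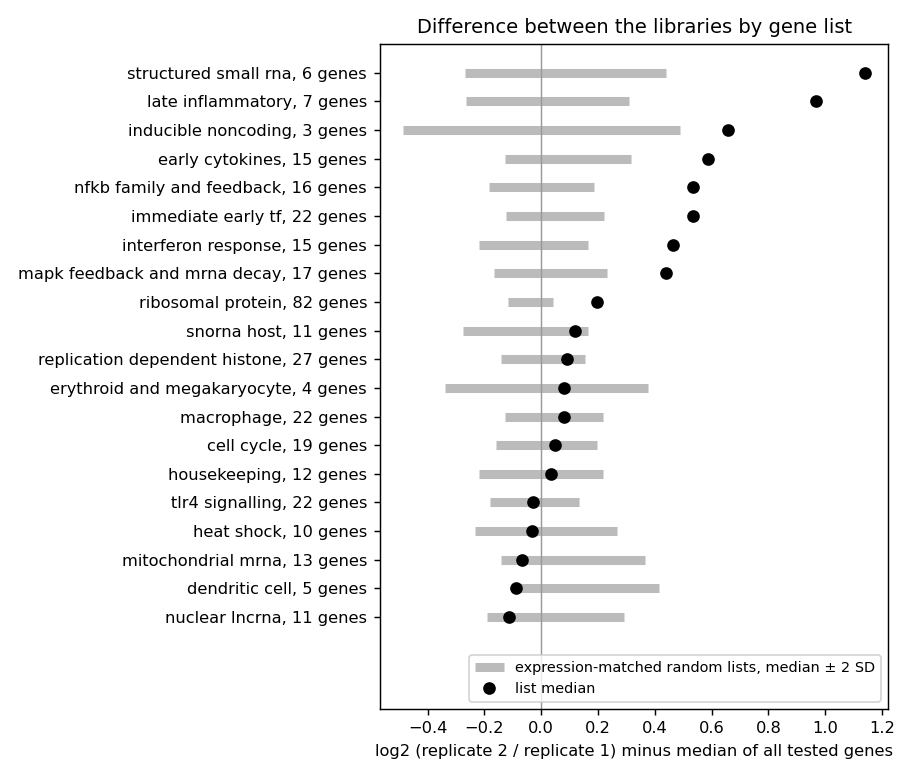
Median log2 ratio of replicate 2 to replicate 1 minus the median of all tested genes (x axis) for lists with at least 3 countable members (y axis), gene table. Grey bars are the median of expression-matched random lists ± 2 SD. The early cytokines are at 0.59 and the immediate early factors at 0.53, which were 0.17 and -0.046 in the alignment-free table, where the NF-kB list was at -0.031 (0.12 for the immediate early factors and 0.13 for the NF-kB list against the genes countable in the gene table) and the macrophage and ribosomal protein lists at -0.39 and -0.37.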

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

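The tests of all shared and of all short-repeat words were chosen before their results were seen, and those weighted by counts or against genes with counts after. A signal outside the comparisons was present in rows that name no mouse gene. The row for phiX, a bacteriophage genome used as a sequencing control, held 47426 counts in replicate 1, 0.350% of all counts (95% Wilson interval 0.347% to 0.353%). It held 14062 in replicate 2, 0.0784% (0.0771% to 0.0797%). The rows with a number as identifier held 39 and 34 counts in all. The phiX totals are above the 3 counts that a count of 0 allows. The 39 and 34 counts are sums over 26248 rows, so this bound for a single row does not apply to them.

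The alignment-free table held signal for 2022 genes that were at 0 in the gene table of both libraries and had at least 10 alignment-free counts in both. Genes at 0 in the gene table took 4.60% (4.59% to 4.61%) of alignment-free counts in replicate 1 and 10.009% (9.997% to 10.020%) in replicate 2, but 53.8% and 83.4% of its TPM. The processed pseudogenes Gm12895 and Gm12896 led, with 353424 and 567566 counts each, followed by the microRNA genes Gm23935, Gm24270 and Gm24245 with 53675 and 443278 each. The genes named here were chosen after their values were seen. Over the 547 pseudogenes and microRNA genes in the set, 1.16% of 31-base words were short repeats, which argues against repeated short units as the source for the set as a whole, and the 5 leading genes, with 96.0% of its counts, had none. For the other genes this stays open: weighted by counts their short-repeat share was 8.58%, with 11.3% in the unprocessed pseudogene Gm29013 and 46.0% and 46.8% in the microRNA genes Gm22406 and Gm25063. Of all words 26.0% lay in transcripts of other genes, between the bounds set for sharing as the source (over 50%) and against it (under 5%), so shared sequence may account for part of the signal and stays open. The words in genes with at least 10 gene-table counts in both libraries were 13.8%, and 0% for the 5 leading genes and the microRNA gene Mir6236; for the leading pseudogenes 99.0% and for the leading microRNA genes 100% of words lay in other genes, all without such counts, which near-identical copies in the set bring about by themselves. No biological explanation was tested.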

How the results depend on the processing

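All 8 differences, of the early lists from the late list and from the interferon list, kept their sign under every alternative run for them. The values that moved by more than the SD between the libraries (for list ratios between the libraries, the SD of random lists) or by over 1.5 times for counts, or that changed sign, follow, and the cause was not tested. Rescaled alignment-free values, ratios minus their median, alignment-free list ratios over the genes countable in the gene table, and means or rescaled TPM for differences were chosen after seeing the data. Lists near 0 have negative levels with a pseudocount of 0.1 because they lie below 1 TPM. Mitochondrial mRNAs and short RNAs are at 0 where rescaling leaves them out. Without a filter the median of all genes is 0, set by genes near 0 in both libraries, so those list ratios are uncentred and their signs show no dependence on the filter. Lists whose median lies below 1 TPM have percentile 0 among detected genes by construction. Another 283 values of these results moved less. Of the alternative TPM values of single genes 87 moved by more than that SD and 121 did not. Of single-gene ratios 29 moved by more than the 95% counting interval and 9 did not. Depth limits genes near 3 counts, such as Ifnb1 and Nos2. List levels with rescaled TPM were 7.06 (immediate early), 7.53 (early cytokine), 5.86 (NF-kB), 5.93 (MAP kinase and mRNA decay), 0.88 (late inflammatory), 5.27 (interferon), 7.36 (macrophage), 0.097 (mast cell), 3.78 (snoRNA host), 0 (small RNA), 0 (mitochondrial mRNA), 5.92 (housekeeping), 4.08 (heat shock), 1.77 (cell cycle), 5.30 (ribosomal protein) and 1.54 (histone). In the alignment-free table, list levels were 5.14 (immediate early), 5.49 (early cytokine), 4.60 (NF-kB), 4.07 (MAP kinase and mRNA decay), 0.52 (late inflammatory), 3.42 (interferon), 2.996 (TLR4), 5.38 (macrophage), 0.46 (neutrophil), 0.16 (B cell), 0.18 (T and NK cell), 0.18 (mast cell), 1.93 (snoRNA host), 3.84 (small RNA), 1.16 (inducible noncoding), 10.17 (mitochondrial mRNA), 3.96 (housekeeping), 2.78 (heat shock), 1.05 (cell cycle), 3.41 (ribosomal protein) and 0.62 (histone). List levels as means over members were 5.95 (immediate early), 6.88 (early cytokine), 6.02 (NF-kB), 5.19 (MAP kinase and mRNA decay), 1.20 (late inflammatory), 4.31 (interferon), 0.46 (neutrophil), 0.17 (B cell), 0.16 (T and NK cell), 1.03 (erythroid), 0.27 (mast cell), 5.63 (nuclear lncRNA), 3.65 (snoRNA host), 6.73 (small RNA), 2.85 (inducible noncoding), 11.10 (mitochondrial mRNA), 5.94 (housekeeping), 4.14 (heat shock) and 1.81 (cell cycle). In the rescaled alignment-free table, list levels were 6.77 (early cytokine), 5.86 (NF-kB), 5.31 (MAP kinase and mRNA decay), 0.91 (late inflammatory), 4.63 (interferon), 0.77 (neutrophil), 0.29 (B cell), 0.34 (T and NK cell), 0.22 (erythroid), 0.30 (mast cell), 0.47 (fibroblast), 5.19 (nuclear lncRNA), 2.92 (snoRNA host), 0.33 (small RNA), 0 (mitochondrial mRNA) and 5.19 (housekeeping). List levels with a pseudocount of 0.1 TPM were -0.55 (late inflammatory), -1.77 (neutrophil), -2.66 (B cell), -2.84 (T and NK cell), -1.01 (dendritic cell), -2.53 (erythroid), -2.81 (mast cell), -2.40 (fibroblast), 0.82 (cell cycle) and 0.51 (histone). Over members with at least 10 counts, list levels were 0.96 (late inflammatory), 4.87 (interferon), 1.09 (neutrophil), 0.44 (B cell), 0.80 (T and NK cell), 1.80 (erythroid), 1.25 (mast cell), 0.42 (fibroblast), 11.80 (small RNA) and 1.74 (histone). List percentiles among lists of detected genes were 100.0 (NF-kB), 0 (late inflammatory), 99.6 (interferon), 95.1 (TLR4), 0 (neutrophil), 0 (T and NK cell), 0 (dendritic cell), 0 (erythroid), 0 (mast cell), 0 (fibroblast), 93.2 (nuclear lncRNA), 72.4 (snoRNA host), 99.9 (small RNA), 2.23 (inducible noncoding), 100.0 (housekeeping), 64.7 (heat shock), 0 (cell cycle) and 0 (histone). Among unmatched lists, list percentiles were 51.3 (late inflammatory), 100 (TLR4), 39.2 (neutrophil), 37.3 (dendritic cell), 8.04 (erythroid), 97.9 (snoRNA host), 73.7 (cell cycle) and 81.5 (histone). Differences from the late list with a pseudocount of 0.1 TPM were 7.07 (immediate early), 7.54 (early cytokine), 5.85 (NF-kB) and 5.93 (MAP kinase and mRNA decay). Over members with at least 10 counts, differences from the late list were 5.57 (immediate early), 6.04 (early cytokine), 4.38 (NF-kB) and 4.45 (MAP kinase and mRNA decay). Differences from the late list in the alignment-free table were 4.62 (immediate early), 4.97 (early cytokine), 4.08 (NF-kB) and 3.55 (MAP kinase and mRNA decay). In CPM, differences from the late list were 7.02 (immediate early), 6.43 (early cytokine), 6.18 (NF-kB) and 5.71 (MAP kinase and mRNA decay). Differences from the late list in the rescaled alignment-free table were 5.50 (immediate early), 5.85 (early cytokine), 4.95 (NF-kB) and 4.40 (MAP kinase and mRNA decay). As means over members, differences from the late list were 4.75 (immediate early), 5.68 (early cytokine), 4.82 (NF-kB) and 3.99 (MAP kinase and mRNA decay). Differences from the late list with rescaled TPM were 6.18 (immediate early), 6.65 (early cytokine), 4.97 (NF-kB) and 5.04 (MAP kinase and mRNA decay). Differences from the interferon list in CPM were 2.06 (immediate early), 1.47 (early cytokine), 1.23 (NF-kB) and 0.75 (MAP kinase and mRNA decay). With a pseudocount of 0.1 TPM, differences from the interferon list were 2.29 (early cytokine) and 0.67 (MAP kinase and mRNA decay). Differences from the interferon list over members with at least 10 counts were 2.13 (early cytokine), 0.47 (NF-kB) and 0.54 (MAP kinase and mRNA decay). In the alignment-free table, differences from the interferon list were 2.07 (early cytokine) and 1.18 (NF-kB). Differences from the interferon list in the rescaled alignment-free table were 2.14 (early cytokine), 1.23 (NF-kB) and 0.68 (MAP kinase and mRNA decay). As means over members, differences from the interferon list were 2.57 (early cytokine), 1.71 (NF-kB) and 0.88 (MAP kinase and mRNA decay). Differences from the interferon list with rescaled TPM were 2.26 (early cytokine). List ratios between the libraries with a pseudocount of 0.1 TPM were 0.65 (immediate early), 0.70 (early cytokine), 0.65 (NF-kB), 0.55 (MAP kinase and mRNA decay), 1.46 (late inflammatory), 0.58 (interferon), 0.013 (TLR4), 0.19 (macrophage), -0.52 (dendritic cell), 0.047 (mitochondrial mRNA), 0.14 (housekeeping), 0.077 (heat shock), -0.0047 (cell cycle) and 0.30 (ribosomal protein). Without a filter, list ratios between the libraries were 0.11 (immediate early), 0.16 (early cytokine), 0.11 (NF-kB), 0.015 (MAP kinase and mRNA decay), 0.098 (late inflammatory), 0.059 (interferon), -0.45 (TLR4), -0.33 (macrophage), -0.43 (dendritic cell), -0.11 (erythroid), -0.56 (nuclear lncRNA), -0.31 (snoRNA host), 0 (small RNA), 0.23 (inducible noncoding), -0.49 (mitochondrial mRNA), -0.39 (housekeeping), -0.46 (heat shock), -0.32 (cell cycle), -0.22 (ribosomal protein) and -0.079 (histone). List ratios between the libraries in the alignment-free table were -0.046 (immediate early), 0.17 (early cytokine), -0.031 (NF-kB), 0.042 (MAP kinase and mRNA decay), 0.65 (late inflammatory), 0.019 (interferon), -0.26 (TLR4), -0.39 (macrophage), 0.74 (dendritic cell), -0.075 (erythroid), -0.37 (nuclear lncRNA), -0.11 (snoRNA host), 0.61 (small RNA), 0.25 (inducible noncoding), -0.62 (mitochondrial mRNA), -0.52 (housekeeping), -0.43 (heat shock), 0.20 (cell cycle), -0.37 (ribosomal protein) and 0.47 (histone). With TMM scaling, list ratios between the libraries were 0.81 (NF-kB), 0.28 (macrophage), -0.39 (dendritic cell), 0.34 (snoRNA host), 1.49 (small RNA), 0.18 (mitochondrial mRNA), 0.13 (heat shock), -0.030 (cell cycle) and 0.29 (ribosomal protein). List ratios between the libraries with DESeq2 size factors were 0.81 (NF-kB), 0.60 (MAP kinase and mRNA decay), 1.54 (late inflammatory), 0.29 (macrophage), -0.54 (dendritic cell), 0.35 (snoRNA host), 1.61 (small RNA), 0.18 (mitochondrial mRNA), 0.13 (heat shock), -0.039 (cell cycle) and 0.31 (ribosomal protein). With at least 100 counts, list ratios between the libraries were 0.027 (TLR4) and 0.29 (snoRNA host). List ratios between the libraries in the alignment-free table over the genes countable in the gene table were 0.12 (immediate early), 0.33 (early cytokine), 0.13 (NF-kB), 0.20 (MAP kinase and mRNA decay), 0.82 (late inflammatory), 0.17 (interferon), -0.26 (macrophage) and -0.21 (ribosomal protein). Retained-intron shares (%) in the alignment-free table were 17.5 (all protein-coding genes), 5.32 (immediate early), 19.9 (NF-kB), 15.9 (MAP kinase and mRNA decay), 3.27 (late inflammatory), 4.16 (macrophage), 61.9 (snoRNA host) and 27.5 (ribosomal protein). Class shares (%) as shares of TPM were 5.70 (mitochondrial-encoded), 0.268 (ribosomal protein), 0.0161 (replication-dependent histone), 2.70 (nuclear lncRNA) and 26.2 (structured small RNA). Without mitochondrial genes in the total, class shares (%) were 0.182 (ribosomal protein), 0.0134 (replication-dependent histone) and 14.1 (nuclear lncRNA). Genes over 2-fold higher and lower in replicate 2 numbered 85 and 1789 with a pseudocount of 0.1 TPM, 241 and 65 with TMM scaling, 420 and 278 with DESeq2 size factors, 301 and 1011 without a filter, 19 and 274 with at least 100 counts, 15 and 13912 in the alignment-free table, 178 and 71 after subtracting the median and 623 and 694 in the alignment-free table minus its median. Of single genes named for their ratio, the sign changed in the alignment-free table for Nr4a1 (-0.60) and Junb (-0.18). It also changed for CT010467.1, whose TPM fell there from 1648 in replicate 1 to 542 in replicate 2, more than the median of all genes. Agreement between libraries had a Pearson r of 0.9472 with a pseudocount of 0.1 TPM, a Pearson r of 0.9771 over genes with at least 10 counts and a Spearman rho of 0.9747 over genes with at least 10 counts. With a TPM of at least 5, 7115 genes and 6294 protein-coding genes were detected. The median share of the leading transcript was 66.8% in the alignment-free table. With 1 library left out, list percentiles ranged from 100.0 to 100.0 (TLR4), from 63.1 to 73.3 (neutrophil), from 6.11 to 17.4 (B cell), from 9.11 to 23.0 (T and NK cell), from 44.1 to 61.0 (erythroid), from 6.80 to 22.4 (fibroblast), at 100.0 (snoRNA host), from 97.9 to 98.7 (heat shock), from 64.9 to 67.8 (cell cycle) and from 100.0 to 100.0 (histone).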

Other observations

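The tests of cytoplasmic RNA and of a later point of the response were chosen after the result was seen, and those of GC content, gene length and exon number before it. The members of the lipid A lists did not move alike between the libraries. For genes with at least 10 counts in both, the ratio of replicate 2 to replicate 1 was taken from TPM + 1 in the gene table. It lay above the median ratio of all genes for 17 of 22 immediate early factors, 12 of 15 early cytokines and 14 of 16 of the NF-kB list. The same held for 13 of 17 of the MAP kinase and mRNA decay list and 6 of 7 late genes. Relative to that median, the AP-1 genes Jun and Junb were at 0.75 and 0.38 log2 units and the nuclear receptor gene Nr4a1 at 0.12, with Junb at -0.18 and Nr4a1 at -0.60 in the alignment-free table, while Fos and Fosb were at -0.48 and -0.80, Nr4a2 at -1.42 and Ptgs2 at -0.82. The chemokine genes Ccl2 and Cxcl10 were at 1.43 and 1.25, the NF-kB target Birc3 at 1.17, Acod1 at 1.51 and Egr3 at 1.16. Outside the lipid A lists, the microRNA host Mir155hg of the inducible noncoding list was at 1.52, and the costimulatory genes Cd40 and Icosl, in none of the lists, were at 1.75 and 1.70. Each of these ratios kept its sign with TMM scaling and, apart from those of Junb and Nr4a1, in the alignment-free table, where Jun stood at 0.21, Fos stood at -1.02, Nr4a2 at -2.28, Ccl2 at 0.87, Cd40 at 0.74 and Birc3 at 0.26. These alignment-free values are against the genes countable there (median -1.19). Against the genes countable in the gene table (median -1.35), a step chosen after seeing the data, each would be higher by the same amount. Junb would then lie almost at the median. Jun, Fosb, Nr4a2, Ccl2, Cxcl10, Birc3, Egr3, Cd40 and Icosl were chosen after their values were seen.

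The 4 early lists stood high in replicate 2 in the gene table, but the immediate early (-0.046) and NF-kB (-0.031) lists did not in the alignment-free table against the genes countable there, and stood at 0.12 and 0.13 against the genes countable in the gene table, which leaves the quantification open as a source of part of the difference. Genes at 0 in the gene table took 53.8% and 83.4% of alignment-free TPM, which lowers the TPM of all other genes in replicate 2. The pseudocount damps this fall more in genes of low TPM, so alignment-free list ratios also depend on the level of a list. Macrophage and housekeeping genes stood lower there than the early lists. The 70 genes of the 4 lists had a pooled median of 0.51, at percentile 100 of 10000 random lists matched on expression and GC content, and likewise at 100 for gene length and 100 for number of exons, which argues against each of these alone as the whole cause. More cytoplasmic RNA in replicate 1 predicts nuclear long noncoding RNAs moving at least as far as the early lists, but in the gene table their median of -0.11 lay -0.62 log2 units from the pooled median, beyond the SD of their members (0.43), which argues against this as the whole cause there, while in the alignment-free table the difference of -0.38 was within that SD (0.56). A later point of the response in replicate 2 is a candidate explanation that predicts the immediate early list falling against the NF-kB list; the difference of their medians was -0.00050, at percentile 51.9 of shuffled lists, which decides nothing. The design has no group that gives a biological explanation to test. The libraries also differed in RNA input by label, 500 ng in replicate 1 and 1 µg in replicate 2. The median difference between length and effective length was 215 and 184 bases. With 1 library on each side, the effect of such preparation differences cannot be told apart from other causes.

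For Malat1, the share of counts was similar in the libraries while TPM was not. Its share of counts was 10.22% (10.21% to 10.24%) in replicate 1 and 10.66% (10.64% to 10.67%) in replicate 2, while its TPM was 32010.2 and 15373. The leading transcript took 44.2% and 78.6% of it. Xist was present in both libraries at 357 and 345 TPM, while of 4 Y-linked genes Kdm5d had 14 and 2 counts, Uty 2 and 0, and Ddx3y and Eif2s3y 0 in both. These Y-linked genes were chosen after their values were seen. The labels give no sex.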
